A study of Homo sapiens with 6 samples.

How the data were processed

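Total RNA of 6 cultures of PC3, an established human prostate cancer cell line, was measured on Affymetrix Human Transcriptome arrays after transient transfection with a synthetic miR-130a precursor (3 arrays) or a negative control precursor (3 arrays). Per the labels' protocols, RNA was biotin-labelled with the GeneChip WT PLUS kit. The deposited table holds log2 expression values that the authors obtained with RMA (background correction, quantile normalization between arrays and summarization of probes) in Affymetrix Expression Console, per the submitters' processing notes, which name no versions. The scale is not stated in the sources used here; it was taken as log2 from the range of the values, and neither rows nor columns were centred. The genome build is not given in the sources used here, so no coordinates are printed.

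The table has 70753 rows, of which 3225 were empty on every array and 67528 held values. GEO's platform annotation gave 1 gene symbol for 23781 of the rows with values, several symbols for 1543 and none for 42204. Only rows with 1 symbol were named. Symbols were updated through Entrez identifiers with NCBI's gene table (assembly GRCh38.p14, used only for names, biotypes and overlapping genes), which matched 21497 of the 23781 rows. For the 479 genes with more than 1 row, the row with the highest mean over all 6 arrays was used, which left 22465 genes, 17085 of them protein-coding. Genes without a row of their own under these rules were not analysed here: 537 of the 623 genes of the fixed lists were measured, and none of the mitochondrially encoded genes, so 30 of 31 lists were tested. Scanner files, detection calls and scan dates were not used here. The number of arrays therefore limits the precision, and background could be judged only from the level of a row.

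The arms were compared with limma (version 3.58.1, R 4.3.3): lmFit and eBayes on the log2 values of the 6 arrays, miR-130a minus negative control, two-sided, with Benjamini-Hochberg adjustment over the 22465 genes and a threshold of 0.05. Every fold change is 2 to the power of the difference of mean log2 values. SE is limma's moderated standard error of the log2 difference, also where it stands beside a fold, unless another is named. Array summaries compress differences, so the folds are those of the array. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists, and again with an estimated correlation. With the estimated correlation, camera called 0 lists (3 at an unadjusted p below 0.05), whereas 18 passed with the preset one. fry, which tests whether a list's genes move on balance one way, gave 16 lists and its mixed form, which tests for change in either direction, gave 27.

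The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule names the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose miR-130a and control values do not overlap, the 4 measured members of each list with the smallest p, and MIR130A, SEC23B and DEPDC1. Genes named outside the rule, which are the remaining members of lists with few called genes and the genes of the closing section's further lists, were chosen after their values were seen. Alternatives were the replicate number as a fixed or random block, a filter on dim rows (mean above 4.995, the median of all rows), a second quantile normalization, median centring, the mean of all rows of a gene, array weights, eBayes with trend and robust options, all 67528 rows, a threshold of at least 1.5-fold, and leaving out each array. A planned comparison of genes with and without miR-130a seed matches in their 3' UTRs was not run, because no transcript sequences were used here. 9 further gene lists, used in the closing section, were written after the results of the fixed lists had been seen. The comparison was simulated 5 times with the means and spreads of the 22465 genes and 200 changed genes. In these simulations limma recovered 73.2% of genes changed 1.5-fold and 95.2% of genes changed 2-fold, and 4.64% of the called genes were false. The simulated noise was normal, with the same spread of a gene on every array. It held no deviating array and no correlation between genes, so these shares need not hold for the measured arrays.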

Results

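Gene expression was profiled in PC3 cells, a human prostate cancer line derived from a bone metastasis, after transient transfection with a precursor of miR-130a, a microRNA that represses messenger RNAs carrying matches to its seed, or with a negative control precursor. The comparison asks which transcripts change when miR-130a is supplied. Each arm comprised 3 arrays, described in the series as independent experiments. The median log2 value over 67528 rows was 4.974, 4.964 and 5.084 on negative control arrays 1, 2 and 3, and 4.995, 4.965 and 4.997 on miR-130a arrays 1, 2 and 3. The miR-130a arrays correlated with each other at r = 0.9964 to 0.9967 over all rows. Negative controls 1 and 2 correlated at r = 0.9958, whereas negative control 3 correlated with them at 0.992 and 0.9923, below its correlation with the miR-130a arrays (0.9931 to 0.9935).

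With miR-130a, 950 of 22465 genes changed at an adjusted p below 0.05 (limma), 558 of them higher and 392 lower. Protein-coding genes made up 523 of the rises and 356 of the falls. The changes were mostly small: 136 genes reached 1.5-fold, 105 upwards and 31 downwards, and 23 reached 2-fold. At an unadjusted p below 0.05, 3707 genes differed. The miR-130a and control values of all 950 genes did not overlap, a pattern shown by 23.6% of all genes against 10% by chance. The count depended on the array that stood apart. Without negative control 3, 2252 genes passed, 1097 higher and 1155 lower, and 938 of the 950 were among them with the same sign. Leaving out any of negative control 1 (397 genes), miR-130a 1 (250), miR-130a 2 (367) or miR-130a 3 (237) lowered the count by more than 1.5 times. A fit with 1 array fewer also has less power, so calls lost in such fits need not mark dependence on the array left out. The row for MIR130A, the gene of the transfected microRNA, lay at 3.37 ± 0.21 (SD, n = 3) in controls and 3.66 ± 0.16 (SD, n = 3) with miR-130a, among the dim rows, and did not pass the test (adjusted p = 0.265, limma). Whether its probes read the transfected precursor is not known here, so the row is no check of the transfection.

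The largest rise was that of CHAC1, a glutathione-degrading enzyme induced by amino acid and endoplasmic reticulum stress, which rose 3.23-fold, from 7.86 ± 0.06 to 9.55 ± 0.04 (log2, SD, n = 3 per arm; difference 1.69, SE 0.054, adjusted p = 6.28e-05). The interstitial collagenase MMP1 rose 2.87-fold and the stromelysin MMP10 rose 2.75-fold, with differences of 1.52 (SE 0.061) and 1.46 (SE 0.060). MAB21L3 rose 2.68-fold, the cytokine IL1A 2.38-fold, and ERN1, the IRE1 sensor of unfolded proteins, 2.36-fold. THBS1, which encodes the matrix protein thrombospondin, rose 2.24-fold, and STC2, a secreted stress-induced glycoprotein, 2.21-fold. The cytokine gene TNFSF15 rose 2.19-fold, the cystine transporter SLC7A11 rose 2.17-fold, the serine protease inhibitor SERPINB4 rose 2.14-fold, and SESN2, a stress-induced inhibitor of mTORC1, rose 2.13-fold. SERPINB4 has a near-identical paralog, SERPINB3, so its value is uncertain. TNFSF15 and SERPINB4 lay at 4.61 and 4.47 in controls, below the dim cut of 4.995, and at 5.75 and 5.57 with miR-130a. Both passed the filter on dim rows only through the miR-130a arrays. The adjusted p of these 12 genes lay between 6.28e-05 and 0.0015 (limma), and all 12 passed under each of the settings run.

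The largest falls were smaller in fold than these rises. SFT2D2, a vesicle transport gene, fell from 8.67 ± 0.12 to 7.65 ± 0.07 (log2, SD, n = 3 per arm), 2.02-fold lower (difference -1.02, SE 0.074, adjusted p = 0.000911). HPRT1, the purine salvage enzyme often used as a reference gene, was 2.02-fold lower (difference -1.01, SE 0.081, adjusted p = 0.00127). The gamma and beta subunits of the epithelial sodium channel, SCNN1G and SCNN1B, were 1.94-fold and 1.73-fold lower. FAM111B was 1.93-fold lower, PDZD11 1.87-fold, the cohesin acetyltransferase ESCO2 1.77-fold, and ANKRD52 1.74-fold. CDK19, a Mediator kinase, was 1.70-fold lower, CBFB, the partner subunit of RUNX factors, 1.69-fold, and the ubiquitin ligase UBE3C 1.67-fold. The transcription factor MYBL1 was 1.74-fold lower (difference -0.80, SE 0.114, adjusted p = 0.0106). Its fall missed the threshold without negative control 1 (adjusted p = 0.052) or miR-130a 3 (adjusted p = 0.0595), and the mean of its rows gave a difference of -0.489. The other 11 falls passed under each of the settings run.

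**Figure D1:**
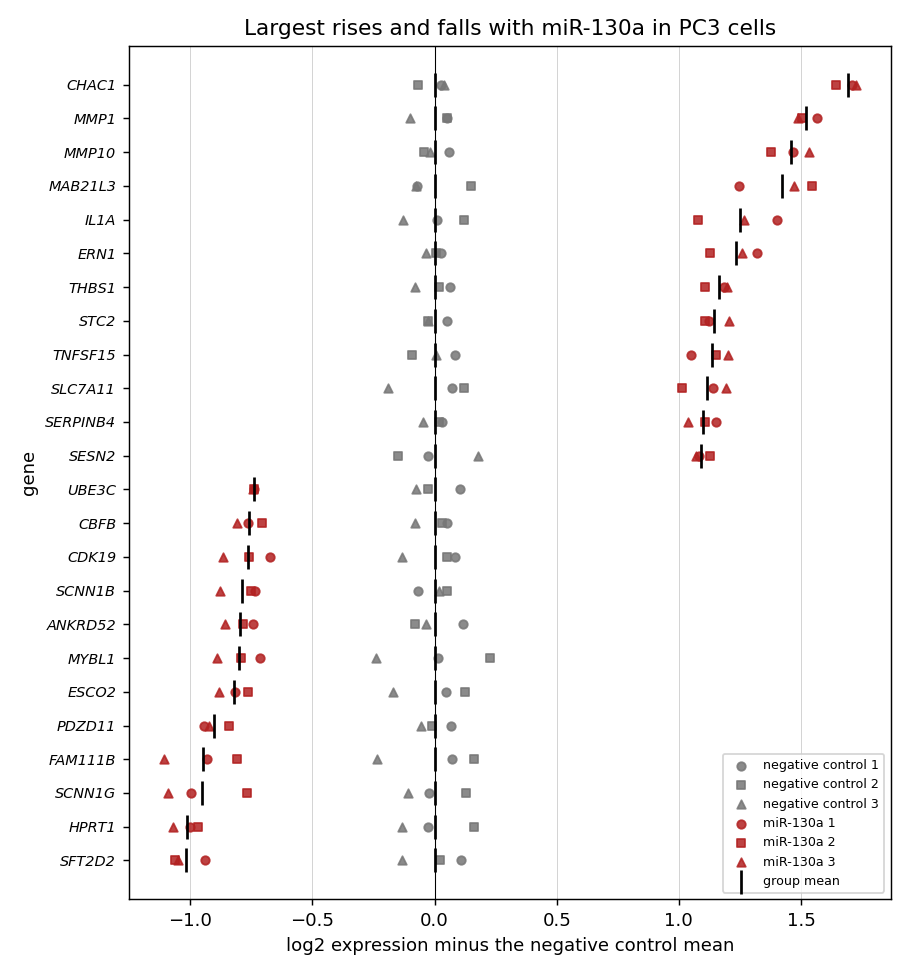
Log2 expression of the 12 genes with the largest rise and the 12 with the largest fall, each as the difference from the gene's mean over the 3 negative controls (x axis, log2 units); a point is 1 array and a black bar is the group mean. The rule that named the genes required the 3 miR-130a arrays to lie apart from the 3 controls on each row. Mean differences run from 1.69 for CHAC1 to -1.02 for SFT2D2.

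SEC23B and DEPDC1 fell. They were taken as genes the study examined as miR-130a targets from recollection of its publication, not from the labels, so this description of them is uncertain. SEC23B, a coat component of COPII vesicles that leave the endoplasmic reticulum, went from 9.65 ± 0.06 to 9.19 ± 0.01 (log2, SD, n = 3 per arm), 1.38-fold lower (SE 0.052, adjusted p = 0.00418). DEPDC1 went from 7.20 ± 0.22 to 6.58 ± 0.05, 1.54-fold lower (SE 0.104, adjusted p = 0.0183). Both passed when adjusted over the list alone, and the pair's camera adjusted p was 0.000699 downwards (adjusted p = 0.223 with an estimated correlation), but a pair that the study may have picked on these arrays is not independent evidence of its direction. DEPDC1 missed the threshold when any array other than negative control 3 was left out (adjusted p = 0.0568 without negative control 2, 0.0801 without negative control 1, 0.0809 without miR-130a 1, 0.0637 without miR-130a 2 and 0.0952 without miR-130a 3), and passed without negative control 3 (adjusted p = 0.00227). It also missed the threshold when every row was tested (adjusted p = 0.0733).

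Genes named in the literature as targets of the miR-130 family did not pass the test as a group. Of 34 measured, 4 fell, 4 rose and 26 did not pass. Adjusted over the list alone, 13 changed. MYBL1 fell, as did the RNA helicase DDX6 (1.65-fold lower, difference -0.72, SE 0.088, adjusted p = 0.00542), the small-RNA processing enzyme DICER1 (1.37-fold lower, adjusted p = 0.0113) and the fatty acid ligase ACSL4 (difference -0.43). The growth arrest gene GADD45A rose 1.38-fold and the RNA-binding protein gene QKI 1.44-fold, with CSF1 and ZFPM2 each 0.24 higher. The median change was -0.048 (camera adjusted p = 0.168; adjusted p = 0.575 with an estimated correlation). Without negative control 3, 9 fell and 4 rose, and the list passed camera's test downwards (adjusted p = 0.00881, but 0.307 with an estimated correlation). Leaving out 1 of the other arrays left 1 to 3 falls and 1 or 2 rises; QKI missed the threshold without miR-130a 1 or miR-130a 3 (adjusted p = 0.0548 and 0.0595). Among 15 genes of microRNA processing and silencing, DDX6 and DICER1 fell and the other 13 did not pass, with 4 changed when adjusted over the list alone. PAN3 differed by -0.36 (adjusted p = 0.0691) and TNRC6B by -0.26 (adjusted p = 0.0785). The list's camera test gave an adjusted p of 0.0487 downwards (adjusted p = 0.597 with an estimated correlation), which rose to 0.212 without negative control 1, 0.34 without negative control 2 and 0.068 without miR-130a 3. DICER1 missed the threshold without negative control 1, miR-130a 1, miR-130a 2 or miR-130a 3 (adjusted p = 0.0522 to 0.0715), and 5 of the list fell without negative control 3.

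Of 37 genes of G2 and mitosis, 14 fell and none rose, with a median change of -0.275 (camera adjusted p = 1.17e-16; adjusted p = 0.223 with an estimated correlation). Adjusted over the list alone, 25 changed. NUSAP1, a spindle protein, was 1.46-fold lower (SE 0.079, adjusted p = 0.0111), cyclin B1 (CCNB1) 1.37-fold, the centromere chaperone HJURP 0.44 lower on the log2 scale and survivin (BIRC5) 1.30-fold. Of 29 genes of G1/S and DNA replication, 9 fell and none rose, with a median change of -0.222 (camera adjusted p = 6.86e-12; adjusted p = 0.223 with an estimated correlation). Adjusted over the list alone, 15 changed. Cyclin E2 (CCNE2) was 1.49-fold lower (SE 0.091, adjusted p = 0.0151), the replication clamp PCNA 1.36-fold (SE 0.048, adjusted p = 0.0038), and the nucleotide synthesis genes RRM2 and TYMS were each 1.32-fold lower. Negative control 3 itself lay at a mean shift of -0.126 over the G2 and mitosis genes, against 0.0367 and 0.0893 for negative controls 1 and 2 and -0.226 to -0.332 for the miR-130a arrays. Without it, 27 of the G2 and mitosis genes fell; 2 fell without negative control 1, 7 without negative control 2, 1 without miR-130a 1, 6 without miR-130a 2 and 0 without miR-130a 3, while the camera test of the list passed in each of these fits. The G1/S falls numbered 2 without negative control 1, 6 without miR-130a 2, 1 without miR-130a 1 and 1 without miR-130a 3. Of the named genes of these lists that fell, only PCNA passed with any 1 array left out; the others missed the threshold without negative control 1, negative control 2, miR-130a 1 or miR-130a 3 in at least 1 case, at an adjusted p of 0.0506 (BIRC5, NUSAP1 and TYMS without negative control 1) to 0.0835 (CCNE2 without miR-130a 3). Among 14 CDK inhibitors, D cyclins and their partners, CDKN2B, which encodes the CDK4/6 inhibitor p15, rose 1.66-fold (SE 0.054, adjusted p = 0.000948), and the other 13 did not pass, CDKN1B being 0.21 higher (adjusted p = 0.0536). The list did not pass (camera adjusted p = 0.125), and 3 of its genes changed when adjusted over the list alone. Leaving out negative control 3 gave 3 rises and 1 fall.

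Of 25 genes of the unfolded protein response, 11 rose and none fell, with a median change of 0.216 (camera adjusted p = 3.98e-12; adjusted p = 0.161 with an estimated correlation). Adjusted over the list alone, 14 changed. The 4 members with the smallest p were CHAC1, ERN1, the pseudokinase TRIB3, which rose 2.05-fold (SE 0.066, adjusted p = 0.000605), and the asparagine synthetase ASNS, which rose 1.76-fold (SE 0.075, adjusted p = 0.00237). DDIT3, outside the naming rule and chosen after its values were seen, rose 2.13-fold (adjusted p = 0.00286). CHAC1, TRIB3 and ASNS are known as targets of the transcription factor ATF4, which amino acid shortage also activates. The rises numbered 12 without negative control 3 and 6 without either miR-130a 1 or miR-130a 3, and the camera test passed in each of these fits. Among 17 p53 target genes, in a line that lacks functional p53, SESN2, GDF15 (2.10-fold, SE 0.078, adjusted p = 0.000911), the death receptor FAS (1.36-fold) and AEN (0.24 on the log2 scale) rose, ZMAT3 was 1.40-fold lower, and 12 did not pass; 6 changed when adjusted over the list alone. SESN2 and GDF15 are also induced by ATF4. The list's median (-0.00494) and its mean (0.149) had opposite signs, and camera gave an adjusted p of 0.0394 upwards (adjusted p = 0.365 with an estimated correlation), lost without negative control 3 (adjusted p = 0.341). FAS missed the threshold without negative control 1, miR-130a 2 or miR-130a 3 (adjusted p = 0.052, 0.0566 and 0.0637), and 2 of the list rose without negative control 1, miR-130a 2 or miR-130a 3.

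Of 20 measured genes of cholesterol metabolism controlled by SREBP factors, 10 rose and none fell, with a median change of 0.261 (camera adjusted p = 2.86e-12; adjusted p = 0.223 with an estimated correlation). Adjusted over the list alone, 12 changed. HMGCS1, an early enzyme of cholesterol synthesis, rose 1.67-fold (SE 0.086, adjusted p = 0.00451), ACAT2 1.53-fold (SE 0.061, adjusted p = 0.00286), squalene epoxidase (SQLE) 1.39-fold and HSD17B7 1.37-fold. The rises numbered 10 without negative control 3, 6 without negative control 1 and 4 without any 1 of the miR-130a arrays. Of 8 genes of cholesterol efflux and LXR action, the transporter ABCG1 was 1.33-fold lower (adjusted p = 0.00483), the fatty acid synthase FASN rose 1.25-fold (adjusted p = 0.0349), and 6 did not pass, LPCAT3 at -0.07 and SCD at -0.05 among them; 2 changed when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.549). FASN missed the threshold when any array other than negative control 3 was left out (adjusted p = 0.0667 to 0.154).

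Of 20 NF-kB targets and cytokines, 9 rose and none fell, with a median change of 0.190 (camera adjusted p = 3.98e-12; adjusted p = 0.172 with an estimated correlation). Adjusted over the list alone, 12 changed. IL1A rose 2.38-fold, the chemokines CCL20 and CXCL1 rose 2.08-fold (SE 0.079, adjusted p = 0.00105) and by 0.58 on the log2 scale (SE 0.052, adjusted p = 0.00205), and the adhesion receptor ICAM1 rose 1.30-fold. The rises numbered 10 without negative control 3, 6 without miR-130a 1 or miR-130a 2, and 4 without miR-130a 3, where ICAM1 was among those lost (adjusted p = 0.057). Of 32 interferon-stimulated genes, only IFIT2 (1.92-fold, SE 0.108, adjusted p = 0.0043) and IFIT5 (1.34-fold, SE 0.072, adjusted p = 0.0203) rose, and none fell; 11 changed when adjusted over the list alone. IFIT3 was 0.45 higher (adjusted p = 0.0594) and the RNA sensor gene IFIH1 0.54 higher (adjusted p = 0.0627). The list's median change was 0.188 (camera adjusted p = 3.83e-09; adjusted p = 0.390 with an estimated correlation). Its mean shift was -0.225 on negative control 1 and 0.115 and 0.111 on negative controls 2 and 3, against 0.197 to 0.304 on the miR-130a arrays. The rises numbered 6 without negative control 3, 5 without negative control 2, and 1 without negative control 1, miR-130a 1 or miR-130a 3, where IFIT5 did not pass (adjusted p = 0.0834, 0.091 and 0.0887).

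**Figure D2:**
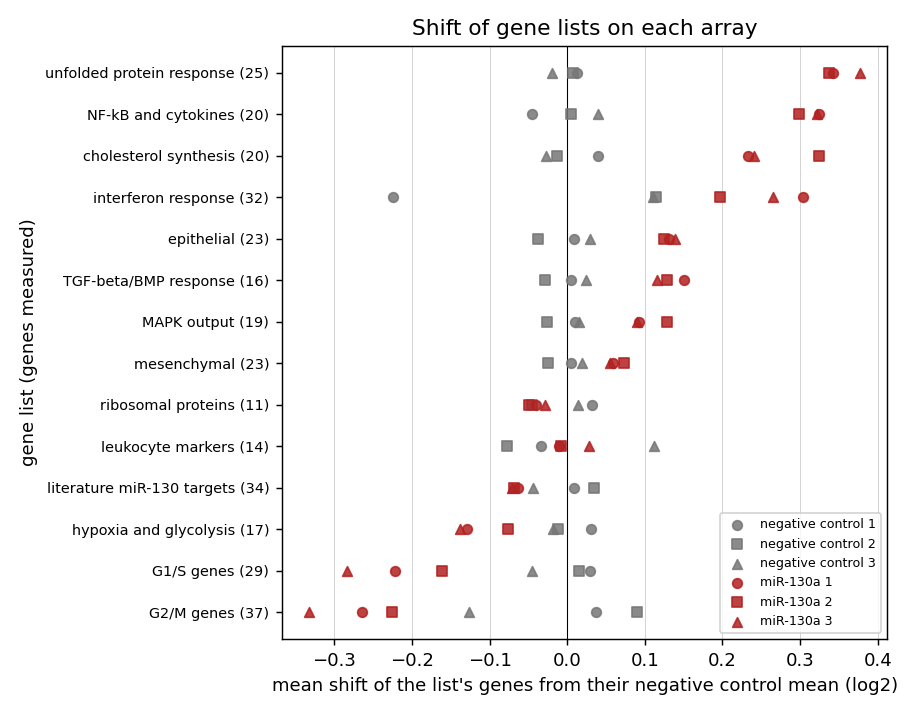
Mean shift of the genes of 14 lists on each array, as the difference of log2 expression from each gene's negative control mean (x axis, log2 units); a point is 1 array, and the number of genes measured stands beside each list. G2 and mitosis genes lie at -0.226 to -0.332 on the miR-130a arrays and -0.126 on negative control 3, and unfolded protein response genes at 0.337 to 0.377 on the miR-130a arrays.

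Of 23 epithelial genes, the tight junction genes CLDN1 (1.99-fold, SE 0.064, adjusted p = 0.000605) and TJP1 (1.31-fold) and the keratin gene KRT18 (1.31-fold) rose and none fell, with ESRP1 0.23 higher (adjusted p = 0.0508), and 8 changed when adjusted over the list alone. The list passed upwards (median 0.0695, camera adjusted p = 0.000699; adjusted p = 0.223 with an estimated correlation), with 7 rises without negative control 3 and 1 without any 1 of the miR-130a arrays. Of 23 mesenchymal genes, fibronectin (FN1, 1.43-fold, adjusted p = 0.00971) and SPARC (1.32-fold) rose, the membrane protease MMP14 was 1.27-fold lower, and the list did not pass (camera adjusted p = 0.0715), with 7 changed when adjusted over the list alone. Of 22 receptors and mediators of TGF-beta and BMP signalling, TGFBR3 (1.40-fold, SE 0.054, adjusted p = 0.00404), SMAD1 (1.28-fold) and SMURF2 (1.27-fold) rose; the list passed (median 0.0760, camera adjusted p = 0.000973; adjusted p = 0.350 with an estimated correlation) but not without negative control 3 (adjusted p = 0.0933). Of 16 response genes of that pathway, the matricellular genes CCN1 (1.88-fold, SE 0.049, adjusted p = 0.000304) and CCN2 (1.51-fold) rose, and ID1 differed by -0.30 (adjusted p = 0.0536; list camera adjusted p = 0.00656; adjusted p = 0.223 with an estimated correlation). Adjusted over each list alone, 8 of the mediators and 6 of the response genes changed. Without 1 of negative control 1, miR-130a 1 or miR-130a 3, each of KRT18, TJP1, SPARC, MMP14, SMAD1 and SMURF2 missed the threshold (adjusted p = 0.0532 to 0.141), as did KRT18, TJP1, SPARC and SMURF2 without miR-130a 2 (adjusted p = 0.0741 to 0.12), MMP14 without negative control 2 (adjusted p = 0.0743), and FN1 without miR-130a 1 or miR-130a 3 (adjusted p = 0.0613 and 0.0548). Without negative control 3, 6 mesenchymal genes, 5 mediators and 4 response genes rose, and 1 mediator fell.

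Of 19 genes that report MAPK activity, 4 rose, the ERK phosphatase DUSP5 (1.74-fold, SE 0.056, adjusted p = 0.000843), MYC (1.24-fold), SPRY2 (1.22-fold) and EPHA2 (0.24 on the log2 scale), and FOSL1 was 1.26-fold lower (list camera adjusted p = 0.00137 upwards; adjusted p = 0.223 with an estimated correlation; 7 changed when adjusted over the list alone). Of 19 genes of PI3K, AKT and mTOR signalling, FOXO3 (1.31-fold, adjusted p = 0.00957), IRS2 (1.32-fold) and DEPTOR (1.21-fold) rose, and 5 changed when adjusted over the list alone; the list's camera adjusted p was 0.00932 upwards (adjusted p = 0.223 with an estimated correlation), and 0.128 without negative control 3, where 5 rose and 2 fell. Of 15 androgen receptor coregulators, the acetyltransferases KAT2B (1.93-fold, SE 0.067, adjusted p = 0.000871) and CREBBP (1.33-fold) and the corepressor NRIP1 (1.29-fold) rose, and 4 changed when adjusted over the list alone; camera gave 0.0179 upwards (adjusted p = 0.533 with an estimated correlation), and 0.45 without negative control 3, where 3 rose and 1 fell. Of 11 androgen-regulated genes of prostate luminal cells, ACP3 alone passed (0.30 higher, from a level of 4.70), and 3 changed when adjusted over the list alone (list camera adjusted p = 0.415). Rises numbered 2 without negative control 3. Apart from DUSP5 and KAT2B, which passed with any 1 array left out, the genes named here missed the threshold in some of these fits. Without miR-130a 1 the adjusted p was 0.0932 for FOSL1, 0.0906 for MYC, 0.156 for SPRY2, 0.0716 for FOXO3, 0.128 for DEPTOR, 0.0548 for CREBBP, 0.0776 for NRIP1 and 0.0984 for ACP3. Without miR-130a 2 or miR-130a 3, MYC, FOSL1, SPRY2, FOXO3, DEPTOR, IRS2, NRIP1 and ACP3 lay between 0.0509 and 0.152, and without negative control 1 FOSL1, SPRY2, DEPTOR, IRS2, NRIP1 and ACP3 between 0.0541 and 0.108. Without negative control 2, DEPTOR and IRS2 did not pass (adjusted p = 0.0594 and 0.0817).

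Of 17 hypoxia and glycolysis genes, 4 fell, BNIP3 (1.30-fold lower, adjusted p = 0.0097), the glucose transporter SLC2A1 (1.29-fold lower), PFKFB3 (1.23-fold lower) and PDK1 (difference -0.31), while VEGFA, the vascular growth factor, rose 1.47-fold (SE 0.053, adjusted p = 0.00255). The list passed downwards (median -0.128, camera adjusted p = 0.000973; adjusted p = 0.223 with an estimated correlation), with 7 changed when adjusted over the list alone; 8 fell without negative control 3, 1 without negative control 1 or miR-130a 2, and 0 without miR-130a 1 or miR-130a 3. Of 29 genes of the COPII and COPI coats and of transport between endoplasmic reticulum and Golgi, SEC23B and SAR1B (1.24-fold lower, adjusted p = 0.0419) fell and MIA3 rose 1.46-fold (SE 0.090, adjusted p = 0.018), with 3 changed when adjusted over the list alone. The SEC23B paralog SEC23A was 0.18 lower and did not pass (adjusted p = 0.15). The list's camera adjusted p was 0.0257 downwards (adjusted p = 0.620 with an estimated correlation), and 0.212 without negative control 1, 0.209 without negative control 2 and 0.118 without miR-130a 1. SAR1B missed the threshold when any array other than negative control 3 was left out (adjusted p = 0.101 to 0.185), and MIA3 when any but negative controls 2 and 3 was (adjusted p = 0.0725 to 0.0938); 6 of the list fell without negative control 3.

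Of 26 autophagy and lysosome genes, SQSTM1 rose by 0.43 on the log2 scale (adjusted p = 0.00553) and ATG16L1 was 1.46-fold lower (adjusted p = 0.00959), and 3 changed when adjusted over the list alone (list camera adjusted p = 0.248). The counts were 2 risen and 3 fallen without negative control 3. Of 18 apoptosis regulators, PMAIP1, which encodes the BH3-only protein NOXA, rose by 0.59 on the log2 scale (adjusted p = 0.00672) and BIRC2 rose 1.37-fold (adjusted p = 0.0464), with 5 changed when adjusted over the list alone (list camera adjusted p = 0.168). There were 3 risen and 2 fallen without negative control 3. Without miR-130a 1 or miR-130a 3, ATG16L1 missed the threshold (adjusted p = 0.0585 and 0.057), as did BIRC2 without negative control 1, miR-130a 1, miR-130a 2 or miR-130a 3 (adjusted p = 0.0957 to 0.187). None of 18 DNA repair genes passed in limma. Only 1, MSH6, differed at an unadjusted p below 0.05 and passed when adjusted over the list alone (difference -0.28, adjusted p = 0.0502 over all genes). The list did not pass (camera adjusted p = 0.549, and 0.821 with an estimated correlation). Without negative control 3, 2 fell and camera's adjusted p was 0.0123 downwards, but 0.343 with an estimated correlation.

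Of 11 genes commonly used as references, HPRT1 and SDHA (1.39-fold lower, SE 0.052, adjusted p = 0.00387) fell and 9 did not pass, with GAPDH at -0.14 (adjusted p = 0.219) and PGK1 at -0.20 (adjusted p = 0.105); 3 changed when adjusted over the list alone. The list passed downwards (median -0.0780, camera adjusted p = 0.00897; adjusted p = 0.223 with an estimated correlation), but not without negative control 2 (adjusted p = 0.0596). None of 11 ribosomal protein genes passed in limma, over all genes or over the list alone, and 0 differed at an unadjusted p below 0.05 (median -0.0438, camera adjusted p = 0.248). Markers of cells other than PC3 did not pass the test as lists: camera's adjusted p was 0.965 for 14 leukocyte markers, 0.519 for 9 fibroblast markers and 0.571 for 8 endothelial markers. The medians of these lists (-0.0152, -0.0305 and -0.0302) were negative while their means (0.003, 0.0259 and 0.0663) and camera's direction were positive. The medians were positive without negative control 3 (0.0655, 0.0262 and 0.0421), and that of the leukocyte markers also without miR-130a 2. Their median control levels were 5.247, 5.498 and 5.958, against 8.284 for the unfolded protein response genes. Single members changed: the macrophage marker CD68, at 10.18 in controls, was 1.37-fold lower (adjusted p = 0.00325), whereas LYZ (1.38-fold, from 4.13), PDGFRA (1.31-fold) and KDR (1.62-fold, adjusted p = 0.00444) rose. Adjusted over each list alone, 3 leukocyte, 1 fibroblast and 1 endothelial marker changed. Of the fibroblast markers, 2 rose without negative control 3. LYZ missed the threshold without negative control 1 or any 1 miR-130a array (adjusted p = 0.0665 to 0.128), and PDGFRA without miR-130a 1 (adjusted p = 0.0507).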

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

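Rows of the table that carry no single gene name took no part in the comparison, and some of them differed between the arms when all 67528 rows were tested together (limma, adjusted over all rows): 99 rose and 72 fell with miR-130a. The largest rises whose arrays did not overlap were rows TC17002746.hg.1, 2.89-fold higher (adjusted p = 0.00332), and TC11003312.hg.1, 2.88-fold higher (adjusted p = 0.00131). The largest falls were rows TC12002644.hg.1, 2.11-fold lower (adjusted p = 0.0273), and TC12003134.hg.1, 1.93-fold lower (adjusted p = 0.0149). Their transcripts were not identified here.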

How the results depend on the processing

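An estimated correlation together with leaving out negative control 3 was added after the data had been seen; the other settings were planned. The direction and the call of 23 of the 24 genes with the largest changes held under each setting run, the exception being MYBL1. The count of 950 changed genes (558 higher, 392 lower) became 616 (222 lower) after median centring and 1449 (654 lower) with trend and robust options; without dim rows 616 genes were lower. Testing all 67528 rows called 448 rows (301 higher, 147 lower), of which 277 were genes among the 950, with the same sign, and 99 higher and 72 lower carry no single gene name. At least 1.5-fold left 136 (105 higher, 31 lower) by construction. Array weights gave 7658 (3551 higher, 4107 lower), with weights from 0.1209 for negative control 3 to 5.64 for negative control 1 from an estimate that stopped before it converged. Leaving out 1 array gave 237 to 2252 genes, 176 to 1097 higher and 61 to 1155 lower, the highest without negative control 3. Each of the 10 splits of the arrays into 3 and 3 was tested: 1 split, the labelled one, gave 950 genes and the highest of the others 0 by limma (1949 at an unadjusted p below 0.05, against 3707), and 10 splits are too few for a share under 0.05. Deviations of same-numbered arrays from their group means correlated at r = -0.0674, 0.0585 and 0.0893. Not every array correlated best with its own number. With 3 arrays per arm, these values cannot decide whether same-numbered arrays shared an experiment. The replicate block gave 818 genes, 723 of them shared with the fit without it. It moved the COPII list (median -0.0446) to a camera adjusted p of 0.0523, with no other list's call changed. Of 135 named genes, 4 gained and 4 lost their call with the block.

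Of 30 lists, 18 passed with the preset correlation, 15 to 18 when 1 array was left out, and 0 with an estimated correlation, with or without negative control 3 (3 each at an unadjusted p below 0.05). The 18 include the pair of study targets, which the study may have picked on these arrays, and the COPII list, which also holds SEC23B. The medians that lost their call with an estimated correlation were -0.542 (study targets), -0.0345 (microRNA machinery), -0.222 (G1/S), -0.275 (G2 and mitosis), -0.00494 (p53 targets), 0.188 (interferon), 0.19 (NF-kB), 0.0695 (epithelial), 0.076 (TGF-beta mediators), 0.0354 (TGF-beta response), 0.0879 (MAPK), 0.113 (PI3K), -0.0446 (COPII), 0.216 (unfolded protein response), 0.261 (cholesterol), -0.128 (hypoxia), 0.0465 (androgen receptor coregulators) and -0.078 (reference genes). fry, which leaves the medians as they are, did not call the microRNA machinery, interferon, COPII and coregulator lists (adjusted p = 0.157, 0.157, 0.184 and 0.0806), and called the CDK inhibitor list (0.0189, adjusted p = 0.0142) and the mesenchymal list (0.0091, adjusted p = 0.0476). The microRNA machinery list lost its call without dim rows (-0.0345) and after centring (-0.0314), the COPII list after centring (-0.0415), and the p53 list after a second quantile normalization (-0.00945). Array weights ended the calls of the p53 (0.00672), TGF-beta mediator (0.0615), PI3K (0.0584) and coregulator (0.0287) lists, called the ribosomal proteins (-0.0716), and turned the sign of the uncalled gene THY1 (0.0201) and camera's direction of the uncalled autophagy list (0.000185). The direction of the uncalled leukocyte list turned without dim rows (-0.0335), after centring (-0.0121) and by fry (-0.0152). Camera's direction of that list also turned without negative control 1, negative control 2 or miR-130a 3. The direction turned for the autophagy list without negative control 3 and for the DNA repair list without negative control 2. The cause of these changes was not tested.

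With 1 array left out, list medians ranged from -0.0676 to -0.0349 (literature targets), -0.0769 to -0.00525 (microRNA machinery), -0.0247 to 0.00944 (p53), 0.0649 to 0.106 (TGF-beta mediators), 0.0624 to 0.106 (PI3K), -0.0739 to -0.0276 (COPII), 0.00642 to 0.0298 (autophagy), -0.0643 to 0.0236 (DNA repair), 0.0253 to 0.0723 (coregulators), -0.087 to -0.0728 (reference genes), -0.0418 to 0.0655 (leukocyte), -0.0588 to 0.0262 (fibroblast) and -0.0611 to 0.0421 (endothelial). They also ranged from 0.0864 to 0.274 (interferon), 0.0289 to 0.113 (epithelial), 0.0227 to 0.0581 (TGF-beta response), 0.0102 to 0.0444 (CDK inhibitors), 0.002 to 0.033 (mesenchymal), 0.0202 to 0.0519 (apoptosis), -0.0715 to -0.0246 (cholesterol efflux), -0.0203 to 0.0736 (prostate luminal) and -0.0554 to -0.0252 (ribosomal proteins). Of the uncalled genes, THY1 ranged from -0.146 to 0.0152, turned without negative control 3, and CLDN5 from -0.0203 to 0.177, turned without negative control 1. Of the 135 named genes, 28 lost their call without negative control 1, 7 without negative control 2, none without negative control 3, 35 without miR-130a 1, 22 without miR-130a 2, 38 without miR-130a 3, 32 when every row was tested and 8 after median centring (BIRC2, TJP1, MMP14, SMURF2, SPRY2, IRS2, SAR1B and FASN). The seed-site comparison and a new background correction were not run. Signal over background was not given, so dim genes such as MIR130A have no measured limit of detection.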

Other observations

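Beyond the lists fixed beforehand, the genes with the largest changes led to 9 further lists, written after those changes had been seen; their tests, and all of those below on negative control 3, on the ATF4 list without that array and on culture conditions, were chosen after the results of the fixed lists had been seen. Of 31 measured genes of the ATF4 amino acid response, 25 rose and none fell, with a median change of 0.539 (camera adjusted p = 3.89e-40 over the 9 lists; adjusted p = 0.0318 with an estimated correlation; 27 changed when adjusted over the list alone). CHAC1, STC2, SLC7A11 and SESN2, whose large rises prompted the list, are among its members, so these p-values partly restate what was seen and are not independent evidence. The risen genes included the cystine and leucine transporters SLC7A11 (1.12) and SLC7A5 (0.67), the serine and one-carbon enzymes PSAT1 (1.06), PHGDH (0.41), SHMT2 (0.50) and MTHFD2 (0.66), and CTH (0.82), an enzyme of cysteine synthesis. Of 19 cytosolic aminoacyl-tRNA synthetases, 9 rose, led by SARS1 (0.54) and WARS1 (0.52), and HARS1 fell (-0.26), with 12 changed when adjusted over the list alone (median 0.305, camera adjusted p = 3.25e-08; adjusted p = 0.124 with an estimated correlation); without negative control 3, 10 rose and 3 fell.

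In other families few members passed. The further lists, the synthetases included, were prompted by changes already seen. Their p-values partly restate what was seen and are not independent evidence. Among 16 matrix metalloproteinases, MMP1 and MMP10 rose and MMP14 fell, and among 7 EGFR ligands only HBEGF passed (0.94). SCNN1B and SCNN1G fell by 0.79 and 0.95 while the alpha subunit SCNN1A differed by 0.01. Among 8 clade B serpins, SERPINB8 rose, as did SERPINB3 and SERPINB4 from dim control levels of 4.84 and 4.47. Among 15 targets of the YAP coactivator, AJUBA (0.92), CCN1, CCN2 and ANKRD1 (0.49, from a dim control level of 4.05) rose. Of 18 deadenylation and decapping genes, DDX6 and CNOT6 (-0.53) fell. Camera's adjusted p, and then that with an estimated correlation, was 0.0288 and 0.32 for the metalloproteinases, 0.0278 and 0.124 for the EGFR ligands, 0.00458 and 0.124 for the sodium channel subunits, 0.000147 and 0.107 for the serpins, 5.29e-05 and 0.0528 for the YAP targets, and 0.346 and 0.742 for the decay genes. Without negative control 3 the EGFR ligands did not pass (adjusted p = 0.154), and the decay genes passed downwards (adjusted p = 0.00748, 3 fallen); 6 YAP targets rose and 1 fell, and 3 metalloproteinases rose and 1 fell. Of 13 microRNA gene rows that passed, 7 overlap another measured gene in NCBI's current annotation, and for 3 of these that gene changed the same way: MIR616 (0.82) with DDIT3 (1.09), MIR3189 (0.63) with GDF15 (1.07), and MIR4737 (0.40) with HEATR6 (0.30).

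A hypothesis is that the rise of ATF4 response genes may be a response apart from a general protein folding load. Against a general folding load that raises such genes as a set, 20 ER chaperone and folding genes had a median change of 0.0122. The bound of 0.18 was a fraction of the ATF4 list's own median (0.539), and the fraction was set before the chaperone median was computed. That list was prompted by rises already seen, so the bound is not independent of these data. The chaperone median lay below the bound by more than its own SE of 0.0463. That SE came from the quartiles over the 20 genes, so it treats them as independent and holds no variation between arrays. HERPUD1, HSPA5 and HYOU1 passed the threshold. Adjusted over the list alone, 6 changed. HERPUD1 (0.57), HSPA5 (0.31), HYOU1 (0.24), EDEM1 (0.23) and DNAJB9 (0.22) were higher and DNAJB11 (-0.30) was lower, so a partial folding load stays open. Of the 20, 15 are also in the unfolded protein response list, whose result had been seen. Against negative control 3 as the source, the median of the ATF4 list was 0.529 without it. A difference in culture density or medium between the arms cannot be told apart from miR-130a, since each arm was its own set of cultures; the hypoxia and glycolysis genes, at a median of -0.128, do not decide it. An effect of miR-130a itself, direct or not, stays open as the difference the design names.

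Negative control 3 stood apart from the other controls: 436 genes deviated from the mean of negative controls 1 and 2 by more than 0.5, against 167 between those 2 arrays and 37 for miR-130a 1 against the other miR-130a arrays. A wrong label is argued against by the slope of its deviation on the miR-130a effect, where 1 would be expected. That slope was 0.24 over the 2252 genes called without negative control 3. Its SE of 0.0113 was taken across genes of 1 array and holds no variation between arrays. The slope stayed above 0 with separate control baselines (0.246 and 0.199), so a partial shift towards the miR-130a arm stays open. RNA of leukocytes, fibroblasts or endothelial cells is argued against by their markers, whose highest excess over genes silent in epithelial lines was 0.0348 on this array; the brightest marker of each kind in controls was CD68 (10.18) for leukocytes, COL1A1 (6.83) for fibroblasts and KDR (7.72) for endothelial cells. A raised background with a compressed range is a candidate explanation: 452 olfactory receptor and hair keratin-associated genes lay 0.14 higher on it, against at most 0.0233 on the miR-130a arrays and a gap of 0.0793 between negative controls 1 and 2, and the 2247 brightest genes at -0.0606, although the miR-130a arrays were also lower there (-0.0365 to -0.0595). The 42 rows of the MIR548 family lay at -0.527 on it and at -0.12 to -0.314 on the miR-130a arrays. Lists of bright genes lay less low on it than the brightest genes. The medians were 0.0354 for ribosomal protein genes (control level 9.353) and -0.0128 for reference genes (9.954). G2 and mitosis genes lay at -0.164 on it and at -0.314 to -0.389 on the miR-130a arrays. A raised background therefore need not account for all of the deviation. RNA quality and sequence composition were not tested. Besides a wrong label and RNA of other cells, no biological explanation was tested, since the labels give none for this array.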
